A study of Bos taurus with 8 samples.

How the data were processed

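The study compared bovine expanded blastocysts, preimplantation embryos that hold an inner cell mass inside a fluid-filled trophectoderm, cultured with or without S-adenosylmethionine (SAM), the methyl donor of most cellular methyltransferases. Per the labels' protocols, embryos produced in vitro were split at about 72 h after fertilization, at the 8-cell stage. SAM was added every 3 h, 4 times a day, to a final 2 µM from a 10 µM stock, and controls received medium alone. Expanded blastocysts were collected in 4 pools of 10 embryos per group. RNA of a SAM pool and of a control pool was labelled with Cy3 and Cy5 and hybridized together to a bovine 2-colour oligonucleotide array. Each of the 4 biological replicates was hybridized in both dye orientations, which gave 8 arrays, and the labels call the swapped array a technical replicate. The series' design text speaks of 4 arrays, whereas 8 were given and used here.

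The deposited scanner files hold, per the file headers, the mean and median brightness of each spot and of its local background in the Cy3 and Cy5 channels, as intensity on the scanner's linear scale before any normalization, together with a flag for spots to be ignored. The scanner software and its settings are not given in the sources used here. The submitters' processing notes name limma, with no version. A table of the authors' processed values holds 1 column per array. Set against the scanner values, the authors' deposited columns were the log2 ratio of Cy5 over Cy3 after the authors' normalization, with medians between -0.05 and 0.00. Its direction, log2 scale and centring near 0 were found from this comparison, and its background correction and its normalization method are not given in the sources used here. In the table as used here the probe identifiers are sorted, while the values follow the order of the spots on the array. Matched by spot order, the 8 columns correlated with the scanner-derived log2 ratios at r = 0.952 to 0.997, and all 160 empty cells fell on the 160 flagged spots. Matched by identifier, the correlations were between -0.01 and 0.01, 0 of the empty cells fell on a flagged spot, and 0 of the 43795 probes stood in the same place in both orders. Over 1654 pairs of probes named for the same gene, the mean log2 ratios correlated at r = 0.180 with the scanner files' identifiers and at r = 0.05 with the table's. The table was therefore used in spot order only, as an alternative to the scanner values.

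Scanner values were corrected with limma's normexp method and an offset of 50, and log2 ratios were normalized by loess within each array, with control spots at weight 0 and flagged spots left out. Ratios were turned to log2(SAM/control) on every array, and the swap pair of each replicate was averaged, so that n = 4. Each pair holds both orientations, so a dye effect of equal size in both arrays cancels. SAM and control pools shared each array, so the comparison is paired by construction. A spot was above background where it exceeded the mean + 2 SD of its array's negative control and dark corner spots. A probe was kept where it was above background in at least 4 of the 8 SAM channels or at least 4 of the 8 control channels, which left 27175 of 43795 probes. Mean log2 ratios were tested against 0 with limma (lmFit and eBayes), two-sided, with Benjamini-Hochberg adjustment at 0.05. A laxer count took an unadjusted p under 0.05 with at least a 1.5-fold difference. A gene was represented by its kept probe with the highest mean brightness, which gave 11104 genes.

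Gene names came from a table that pairs the array's probes with platform annotation. It gave 1 symbol for 21790 probes, several for 0 and none for 22005. Symbols were updated through a RefSeq gene table of the assembly ARS-UCD2.0, used only for names and gene classes. In it 20025 probes had a current symbol, 1524 were renamed through a synonym and 241 kept the older symbol. Probes without a symbol are unnamed here.

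The 32 gene lists were written before the data were examined, as were the tests and all alternatives except those said below to be added. They covered the methionine cycle and folate one-carbon metabolism, polyamine synthesis and methionine salvage, and small-molecule methyltransferases. Further lists held DNA methylation, histone methyltransferases, histone demethylases, RNA methylation, imprinted genes, and germline genes silenced by promoter methylation. Lineage lists held pluripotency and inner cell mass, trophectoderm, primitive endoderm, and cavitation with junctions and ion transport. Others held p53 response and apoptosis, oxidative stress, endoplasmic reticulum and amino acid stress, heat shock, cholesterol synthesis, fatty acid metabolism, glycolysis, oxidative phosphorylation, cell cycle, cytosolic ribosomal proteins and histone genes. Signalling lists held interferon-stimulated genes, FGF and MAPK feedback targets, and WNT and HIPPO targets. Markers of other cells covered oocytes, cumulus and granulosa cells, sperm, blood and immune cells, and fibroblast and mesenchymal cells. Lists were tested with camera at a preset correlation of 0.01, adjusted over the 32 lists. The same lists were also tested with an estimated correlation and with fry. A list's median was also set among 10000 random lists matched on brightness in 200 bins.

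Named genes followed a rule with 3 parts. The first took, where fewer than 5 genes passed in a direction, the 5 with the smallest unadjusted p among those that moved the same way in all 4 replicates. Unnamed probes were given by identifier only where they ranked in the first 3 per direction. The second took the 3 members with the smallest p in each list. The third always took *MAT2A*, *MAT2B*, *AHCY*, *MTR*, *DNMT1*, *DNMT3A*, *DNMT3B*, *TET1*, *TET3*, *POU5F1*, *NANOG*, *SOX2*, *CDX2*, *GATA3*, *GATA6* and *IGF2R*. *TET1* and *GATA6* were not among the array's named probes. Genes outside the rule are said to have been chosen after their values were seen.

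The replicate numbers paired the arrays. Deviations of the turned log2 ratios from their mean correlated at r = 0.378 to 0.646 within the 4 swap pairs, and each of the 4 arrays in one orientation was closest to the array of its own number in the other. The numbers come from the labels, which call the second array a dye swap of the same replicate.

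Alternatives were no background correction, normexp with an offset of 16, Aquantile after loess, median centring in place of loess, no filter on dim probes, and above background in all channels. Others were the 8 arrays with a replicate block, with no block, and with a block and a dye term, each replicate left out, each dye orientation alone, array weights, and eBayes with trend and robust options. A fit of the channels with pools unpaired, the deposited values, and the mean over all probes of a gene were also run. In some fits the lists were tested with cameraPR, a form of camera on the genes' test statistics, at the same preset correlation. These were the fits of all 8 arrays, unpaired pools, array weights, and eBayes with trend and robust options. A detection limit from median and MAD, and replicates 3 and 4 alone, were added after seeing the data. Aquantile changed no ratio, since it leaves ratios within an array as they are. A slide block was not run, because the files name no slide.

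The tests were checked on simulated data for the comparison of SAM with control, built from the spread of 11076 genes with 200 genes changed. On 4 replicate means, limma made 173 calls, 8 of them of unchanged genes, and recovered 73.1%, 79.1% and 95.5% of the genes changed 1.5-fold, 2-fold and 3-fold. The fit of 8 arrays with a replicate block and dye term made 225 calls, 42 of them of unchanged genes, well above the nominal share. With no gene changed, both made 0 calls, with 5.19% and 5.72% of genes at an unadjusted p under 0.05. In 20 simulations camera called the shifted list in 20, and 0 of 620 unchanged lists. The simulated genes varied independently and held no dye effect that differed between orientations, so these shares exclude nothing about either. Analyses used R 4.3.3 with limma 3.58.1 and statmod 1.5.0. On arrays, the number of replicates limits the precision.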

Results

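Gene expression was measured in 4 pools of 10 bovine expanded blastocysts cultured with SAM and in 4 control pools, each SAM pool set against a control pool on a pair of dye-swapped arrays. The 8 arrays each held 43795 probes for bovine genes. Median spot brightness was 71.6 to 320.8 in Cy3 and 83.1 to 242.2 in Cy5, against 42.9 to 260.8 and 63.0 to 188.4 at the negative control spots. Between 29.3% and 76.7% of probes were above background in Cy3 and between 19.4% and 56.5% in Cy5. The array with SAM in Cy5 of replicate 2 was the lowest in both channels, with detection limits of 323.3 in Cy3 and 542.3 in Cy5. At most 33 probes per array were saturated. Keratins 8 and 18, abundant in trophectoderm, lay at a mean log2 brightness of 15.1 and 14.8, while *INS*, *ALB* and *CD3E*, genes of the pancreas, liver and T cells, lay between 7.51 and 7.90.

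The first comparison asked which transcripts differed between SAM-treated and control blastocysts. No transcript passed the adjusted threshold. The genes with the smallest unadjusted p lay at 1.41 to 1.54 times the control level where higher and at 0.655 to 0.755 times where lower. Those higher with SAM were *LIN52*, a subunit of the DREAM cell cycle repressor, *FBXL5*, an iron-sensing ubiquitin ligase subunit, *FMR1*, an RNA-binding translational regulator, *BRD9*, a bromodomain subunit of a chromatin remodelling complex, and *LAP3*, a leucine aminopeptidase. Their log2 ratios were 0.62 ± 0.06 for *LIN52*, 0.53 ± 0.05 for *FBXL5*, 0.53 ± 0.06 for *FMR1*, 0.57 ± 0.06 for *BRD9* and 0.49 ± 0.05 for *LAP3* (SE, n = 4 replicates). Those lower with SAM were *BAG1*, a co-chaperone of HSP70, *TMEM45B*, a transmembrane protein, *CARS1*, the cysteinyl-tRNA synthetase, *MRPL46*, a mitochondrial ribosomal protein, and *STUB1*, a chaperone-linked ubiquitin ligase. Their log2 ratios were -0.61 ± 0.07 for *BAG1*, -0.56 ± 0.06 for *TMEM45B*, -0.59 ± 0.07 for *CARS1*, -0.60 ± 0.07 for *MRPL46* and -0.41 ± 0.05 for *STUB1*. At *LIN52* 1 of 2 kept probes and at *FMR1* 2 of 3 pointed this way. *LIN52* was at 0.28 with SAM in Cy3 and 0.97 with SAM in Cy5, and *BAG1* at -0.59 and -0.64. Each of the 10 moved the same way in 4 of 4 replicates, which the rule required of them, so this agreement is not a result. None passed, with a limma adjusted p of 0.146 for each.

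**Figure D1:**
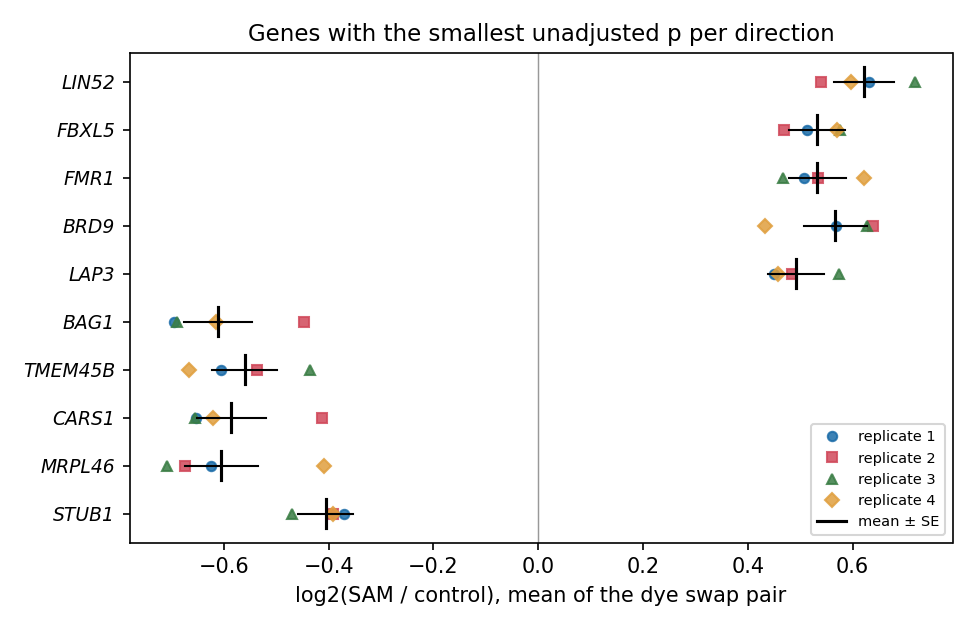
Log2 ratio of SAM over control for the 5 genes with the smallest unadjusted p in each direction, with 1 symbol per replicate and the mean ± SE of 4 replicates as a vertical tick and horizontal bar. Genes were taken only where all replicates lay on the same side of 0. The values lie between 0.43 and 0.72 for the higher genes and between -0.71 and -0.37 for the lower ones.

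Limma called 0 of 27175 probes, with a lowest adjusted p of 0.127, while 5478 had an unadjusted p under 0.05, against 1359 expected by chance alone, and 2858 without replicate 3. Of these, 3098 were higher and 2380 lower with SAM. At an unadjusted p under 0.05 and at least 1.5-fold, 160 probes were counted, 85 higher and 75 lower. Without replicate 1 there were 174 higher and 39 lower, and without replicate 2, 163 and 133. With median centring in place of loess there were 68 higher and 85 lower, and with the deposited values 100 and 103. Among unnamed probes, EMBV3_37628 was higher by a log2 ratio of 0.63 ± 0.04, and EMBV3_18869 and EMBV3_29583 were lower, at -0.95 ± 0.06 and -0.63 ± 0.06 (SE, n = 4), all 3 with a limma adjusted p of 0.127. Over genes, limma called 0 of 11104, with a lowest adjusted p of 0.146, and 2168 had an unadjusted p under 0.05, 1349 higher and 819 lower, and 1188 without replicate 3. Of all kept probes, 33.1% had the same sign in 4 of 4 replicates, against 12.5% by chance.

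Counts of calls depended on how the dye swap was entered. When the 8 arrays were fitted with a replicate block and a dye term, limma called 303 probes and 101 genes, 63 higher and 38 lower. All 101 had the same sign in 4 of 4 replicates and in both dye orientations, which selection by this fit favours, and 18 of the 116 genes named by the rule were among them. They included *LIN52*, *FMR1*, *BRD9*, *LAP3*, *BAG1*, *TMEM45B*, *CARS1*, *MRPL46* and *STUB1*, while *FBXL5* did not pass. The differences of the 101 genes were small, with a median size of 0.47 on the log2 scale. Genes at the top by size, chosen after their values were seen, were *CT47B1*, a cancer/testis antigen family member, at a log2 ratio of 1.21 ± 0.18, *LYZ3*, a lysozyme, at 1.07 ± 0.20, *MXRA7* at 0.85 ± 0.12, with 1 of its 2 kept probes higher, *PRKAG2*, a regulatory subunit of AMP-activated kinase, at 0.77 ± 0.13, and *GBP4*, an interferon-inducible guanylate-binding protein, at 0.76 ± 0.09. In the other direction *RPL7A*, a ribosomal protein, was at -0.97 ± 0.13. Of simulated calls by this fit, 42 of 225 were of unchanged genes, so the 101 genes are less certain than the threshold states. The balance of directions also depended on the fit. Over 8 arrays with a replicate block alone 98 genes were called higher and 119 lower, and with no block 78 and 99. With array weights on the replicate means they were 134 and 34.

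The second comparison asked whether genes that make, use or answer to SAM differed. The methionine cycle and folate list did not move as a group, with a median log2 ratio of 0.05 over 27 members (camera adjusted p = 0.954), 5 members higher and 4 lower at an unadjusted p under 0.05. Member counts at this threshold, here and below, stand against 1349 higher and 819 lower among all 11104 genes. *MAT2A*, the methionine adenosyltransferase that makes SAM, was lower at its brightest probe, at -0.48 ± 0.10 (SE, n = 4, limma adjusted p = 0.146), in 4 of 4 replicates. Its 3 other kept probes were higher in the mean, at 0.16 ± 0.11, 0.11 ± 0.05 and 0.12 ± 0.05, so the probes of *MAT2A* disagreed in direction. *MTFMT*, which formylates the mitochondrial initiator tRNA, was at 0.55 ± 0.11 and *MTHFD1*, a folate-interconverting enzyme, at -0.29 ± 0.08. *MAT2B*, the regulatory subunit, was at 0.27 ± 0.17, *AHCY*, which clears S-adenosylhomocysteine, at 0.05 ± 0.26, and *MTR*, the methionine synthase, at -0.03 ± 0.05. *MTR* was dim, above background in 6 SAM and 5 control channels, so its small ratio does not show an unchanged level. Fitted over 8 arrays with a block and a dye term, the brightest *MAT2A* probe passed.

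Among polyamine synthesis genes, which draw on decarboxylated SAM, 1 member was higher and 3 were lower at an unadjusted p under 0.05, and the median over 14 members was -0.06 (camera adjusted p = 0.406). *SAT1*, which acetylates polyamines for export, was at 0.56 ± 0.11 and *ODC1*, the rate-limiting synthetic enzyme, at -0.35 ± 0.08 (SE, n = 4). These were the 2 members that passed when adjusted over the list alone, against 0 over all genes. *SRM*, the spermidine synthase, was at -0.24 ± 0.08. Small-molecule methyltransferases had a median of 0.00 over 16 members (camera adjusted p = 0.954), with the coenzyme Q methyltransferases *COQ3* at 0.24 ± 0.07 and *COQ5* at -0.27 ± 0.10.

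No list of chromatin or nucleic acid methylation moved as a group. DNA methylation and demethylation had a median of -0.06 over 23 members (camera adjusted p = 0.954), with 0 members higher and 1 lower at an unadjusted p under 0.05. The maintenance methyltransferase *DNMT1* was at 0.13 ± 0.07, the de novo enzymes *DNMT3A* and *DNMT3B* at 0.21 ± 0.11 and -0.22 ± 0.18, and the dioxygenase *TET3* at 0.15 ± 0.21 (SE, n = 4). *DNMT1* was dim, above background in 5 SAM and 5 control channels, so its small ratio does not show an unchanged level. *DNMT3A* and *DNMT3B* each pointed in opposite directions in the 2 dye orientations, *DNMT3A* at -0.08 with SAM in Cy3 and 0.50 with SAM in Cy5, and *DNMT3B* at 0.23 and -0.67. Histone methyltransferases had a median of -0.01 over 35 members (adjusted p = 0.954), with the H3K9 enzyme *SETDB1* at 0.45 ± 0.07 as the 1 member past the threshold adjusted over the list alone. *SETDB1* was at 0.09 with SAM in Cy3 and 0.81 with SAM in Cy5. *PRMT7*, an arginine methyltransferase, was at -0.25 ± 0.05 and *ASH1L*, an H3K36 enzyme, at 0.28 ± 0.06. Histone demethylases had a median of -0.01 over 15 members (adjusted p = 0.954), with *KDM4C* at 0.46 ± 0.14, but -0.07 with SAM in Cy3, and *KDM4B* at -0.18 ± 0.05, but 0.04 with SAM in Cy3. RNA methylation had a median of 0.00 over 31 members (adjusted p = 0.954), with 6 higher and 3 lower at an unadjusted p under 0.05. Adjusted over the list alone, the m6A reader *YTHDF1*, at 0.59 ± 0.07, and the tRNA methyltransferase *TRMT5*, at -0.29 ± 0.05, passed, and *WTAP*, of the m6A writer complex, was at 0.32 ± 0.08.

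Imprinted genes, whose expression follows parental methylation, had a median of 0.00 over 19 members (camera adjusted p = 0.954). *MKRN3*, a paternally expressed gene, was at 0.34 ± 0.05 and was the 1 member past the threshold adjusted over the list alone. *CD81*, a tetraspanin, was at -0.45 ± 0.11 and *IGF2R*, the receptor that clears IGF2, at -0.28 ± 0.10 (SE, n = 4). Germline genes silenced by promoter methylation had a median of 0.07 over 20 members (adjusted p = 0.406), with 3 higher and 1 lower at an unadjusted p under 0.05. *DDX4*, a germ cell helicase, was at 0.31 ± 0.06 and passed adjusted over the list alone, *SYCP3*, of the synaptonemal complex, was at 0.22 ± 0.07, but -0.10 with SAM in Cy5, and *CTCFL*, a testis paralogue of CTCF above background in 4 SAM and 2 control channels, was at 0.16 ± 0.06. Histone genes, linker and variant histones included, had a median of 0.22 over 15 members (adjusted p = 0.163), with 3 higher and 0 lower. These 3 were the linker histone *H1-12*, at 0.19 ± 0.06, and the variants *H2AZ1* and *MACROH2A1*, at 0.33 ± 0.12 and 0.34 ± 0.13, each variant higher in 3 of 4 replicates. *H2AZ1* was at -0.04 with SAM in Cy3, and 1 of 2 kept *MACROH2A1* probes was higher. Without replicate 2 the histone list passed, at an adjusted p of 0.021, the lowest of its alternatives, which reached 0.800.

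The third comparison asked whether markers of the blastocyst's lineages differed. None of the lineage lists passed. Pluripotency and inner cell mass genes had a median of 0.02 over 27 members (camera adjusted p = 0.954), with 3 higher and 2 lower at an unadjusted p under 0.05. *STAT3*, the transcription factor downstream of LIF and IL6, was at 0.53 ± 0.09 at its brightest probe and passed adjusted over the list alone, but 1 of its 3 kept probes pointed this way. *OTX2*, a homeobox factor, was at -0.41 ± 0.09 and *MYC* at 0.40 ± 0.11 (SE, n = 4). The core factors *POU5F1* and *SOX2* were at -0.28 ± 0.12 and 0.02 ± 0.06. *SOX2* was dim, above background in 5 SAM and 4 control channels, so its small ratio does not show an unchanged level. *NANOG* was at -0.87 ± 0.49, with -2.70 in replicate 4 and between -0.75 and 0.31 in the others. Trophectoderm genes had a median of -0.07 over 37 members (adjusted p = 0.555), with 3 higher and 2 lower, and the list's median in replicate 1 was -0.25. *TKDP1*, a trophoblast Kunitz domain protein, was at 0.63 ± 0.14, *CDX2* at -0.20 ± 0.08 and *GATA3* at -0.18 ± 0.08. Primitive endoderm genes had a median of 0.10 over 26 members (adjusted p = 0.253), with 5 higher and 2 lower. The collagen prolyl hydroxylase *P4HA1*, at 0.52 ± 0.08, passed adjusted over the list alone, and the laminin chain *LAMC1* was at 0.46 ± 0.10. *P4HA1* was at 0.16 with SAM in Cy3 and 0.89 with SAM in Cy5. Cavitation, junction and ion transport genes had a median of -0.04 over 32 members (adjusted p = 0.406), with 1 higher and 8 lower. The desmosomal *PKP2* was at 0.33 ± 0.07, the junctional *JUP* at -0.25 ± 0.05 and the polarity gene *PARD3* at -0.26 ± 0.07.

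The fourth comparison asked about energy metabolism, translation and stress. Genes of oxidative phosphorylation, the mitochondrial respiratory chain and ATP synthase, fell as a list with camera at its preset correlation. The median log2 ratio was -0.12 over 82 members (camera adjusted p = 0.013), with an adjusted p = 0.800 with an estimated correlation. With an estimated correlation camera called 0 of 32 lists and 0.800 was the lowest adjusted p, with an unadjusted p of 0.164 for this list. At an unadjusted p under 0.05, 3 members were higher and 18 lower, and 0 passed over all genes or adjusted over the list alone. *NDUFA6*, a complex I subunit, was at -0.30 ± 0.06 and *ATP5MK*, an ATP synthase subunit, at -0.35 ± 0.07, whereas *COX7A2L*, which assembles respiratory supercomplexes, was at 0.44 ± 0.07 (SE, n = 4). *COX7A2L* was at 0.05 with SAM in Cy3 and 0.82 with SAM in Cy5. The list's median was negative in 4 of 4 replicates, from -0.15 to -0.02, and in 7 of 8 arrays. With SAM in Cy3 alone the list also passed as lower, at a camera adjusted p of 0.0071 and a median of -0.09. There its unadjusted p was 0.163 with an estimated correlation. With SAM in Cy5 alone the list did not pass, although its median was -0.17. The median over the 4 replicates lay below all 10000 brightness-matched random lists. Uncalled lists also lay far out, with fibroblast and mesenchymal markers at percentile 99.99 and histone and interferon-stimulated genes each at 99.95. Cytosolic ribosomal protein genes also fell as a list with camera (adjusted p = 0.028), with an adjusted p = 0.800 with an estimated correlation. Their median was -0.04 and their mean -0.09 over 67 members, with 2 higher and 13 lower. The median was negative in 3 of 4 replicates, from -0.08 to 0.01, and lay at percentile 4.44 of the matched random lists, inside their middle 95%. *RPL7A*, at -0.97 ± 0.15, and *RPS12*, at -0.41 ± 0.06, passed adjusted over the list alone, and *RPL11* was at -0.33 ± 0.06. Without replicate 1 the ribosomal list was at an adjusted p of 0.137 and without replicate 4 at 0.099, within a range of 0.00075 to 0.800 over its alternatives. With fry, the 2 lists had adjusted p of 0.363 and 0.419, and over the alternatives oxidative phosphorylation ranged from 0.00048 to 0.800.

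Fatty acid and lipid droplet genes did not move as a group, with a median of -0.03 over 33 members (camera adjusted p = 0.954), 4 higher and 1 lower at an unadjusted p under 0.05. Adjusted over the list alone, 3 were higher, namely the elongase *ELOVL5*, at 0.55 ± 0.07, the mitochondrial beta-oxidation subunit *HADHB*, at 0.43 ± 0.08, and *DGAT2*, which completes triglyceride synthesis, at 0.42 ± 0.09 (SE, n = 4). With SAM in Cy3 *HADHB* was at 0.06 and *DGAT2* at 0.09, against 0.79 and 0.74 with SAM in Cy5. Cholesterol synthesis genes had a median of -0.05 over 24 members (adjusted p = 0.383), with medians of -0.25, 0.08, 0.24 and -0.38 in replicates 1 to 4. The member with the smallest unadjusted p, *GGPS1*, was higher, at 0.18 ± 0.06, in 4 of 4 replicates, but at 0.03 with SAM in Cy3. The acetoacetyl-CoA thiolase *ACAT2* was at -0.62 ± 0.23, and *FDFT1*, the squalene synthase, at -0.38 ± 0.16, each lower in 3 of 4 replicates. Without replicate 3 this list passed, at an adjusted p of 0.0099, the lowest of its alternatives, which reached 0.974. Glycolysis had a median of 0.04 over 24 members (adjusted p = 0.555), with *ENO1* at -0.41 ± 0.11 and *HK2* at 0.29 ± 0.09. Cell cycle and DNA replication had a median of 0.05 over 64 members (adjusted p = 0.604), with 12 higher and 5 lower, and *CCNB1*, the mitotic cyclin, was at 0.46 ± 0.09.

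Stress and signalling lists did not pass. Endoplasmic reticulum and amino acid stress had a median of -0.10 over 32 members (camera adjusted p = 0.555), with 3 higher and 3 lower, and *CARS1* as the 1 member past the threshold adjusted over the list alone. The stress kinase *EIF2AK3* was at 0.27 ± 0.06 (SE, n = 4). The p53 and apoptosis list had a median of -0.04 over 29 members (adjusted p = 0.954), with 5 higher and 1 lower. The death receptor *FAS*, at 0.39 ± 0.06, passed adjusted over the list alone, although it was at 0.02 with SAM in Cy3 and 0.76 with SAM in Cy5. The initiator caspases *CASP9* and *CASP8* were at 0.24 ± 0.05 and 0.54 ± 0.13, *CASP8* above background in 6 SAM and 1 control channels. Oxidative stress and glutathione genes had a median of 0.00 over 42 members (adjusted p = 0.954), with *NFE2L2*, the master antioxidant regulator, at 0.36 ± 0.09 and *PRDX2*, a peroxiredoxin, at -0.29 ± 0.08. Heat shock genes had a median of -0.01 over 20 members (adjusted p = 0.954), with the co-chaperone *BAG3* at -0.28 ± 0.07. The next members by p went the other way, *HSF2* at 0.20 ± 0.07 and *SERPINH1* at 0.32 ± 0.13. FGF and MAPK feedback targets had a median of -0.03 over 24 members (adjusted p = 0.797), and *KLF6*, a zinc finger factor, at -0.42 ± 0.07, passed adjusted over the list alone. WNT and HIPPO targets had a median of -0.07 over 26 members (adjusted p = 0.608), with *CCN2*, a matricellular HIPPO target, at 0.84 ± 0.20 and the angiomotin *AMOT* at 0.41 ± 0.12.

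Over all 32 lists, 0 members passed among all genes tested and 17 passed adjusted over the list alone, in 12 lists. Fry called 1 list for movement in one direction, cumulus and granulosa cells, and 21 for change in either direction. Fry tests a list against no change in its own members, whereas camera sets it against the other genes. With 2168 of all 11104 genes at an unadjusted p under 0.05, these 21 calls do not set the lists apart from other genes. Without replicate 1 or replicate 4 camera called 1 list, and without replicate 3 it called 4. The median over all genes was 0.00. In 7 lists the median, mean and test differed in sign, none of them called. Median and mean differed for oxidative stress, p53, histone methyltransferases, histone demethylases, sperm, RNA methylation and imprinted genes.

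**Figure D2:**
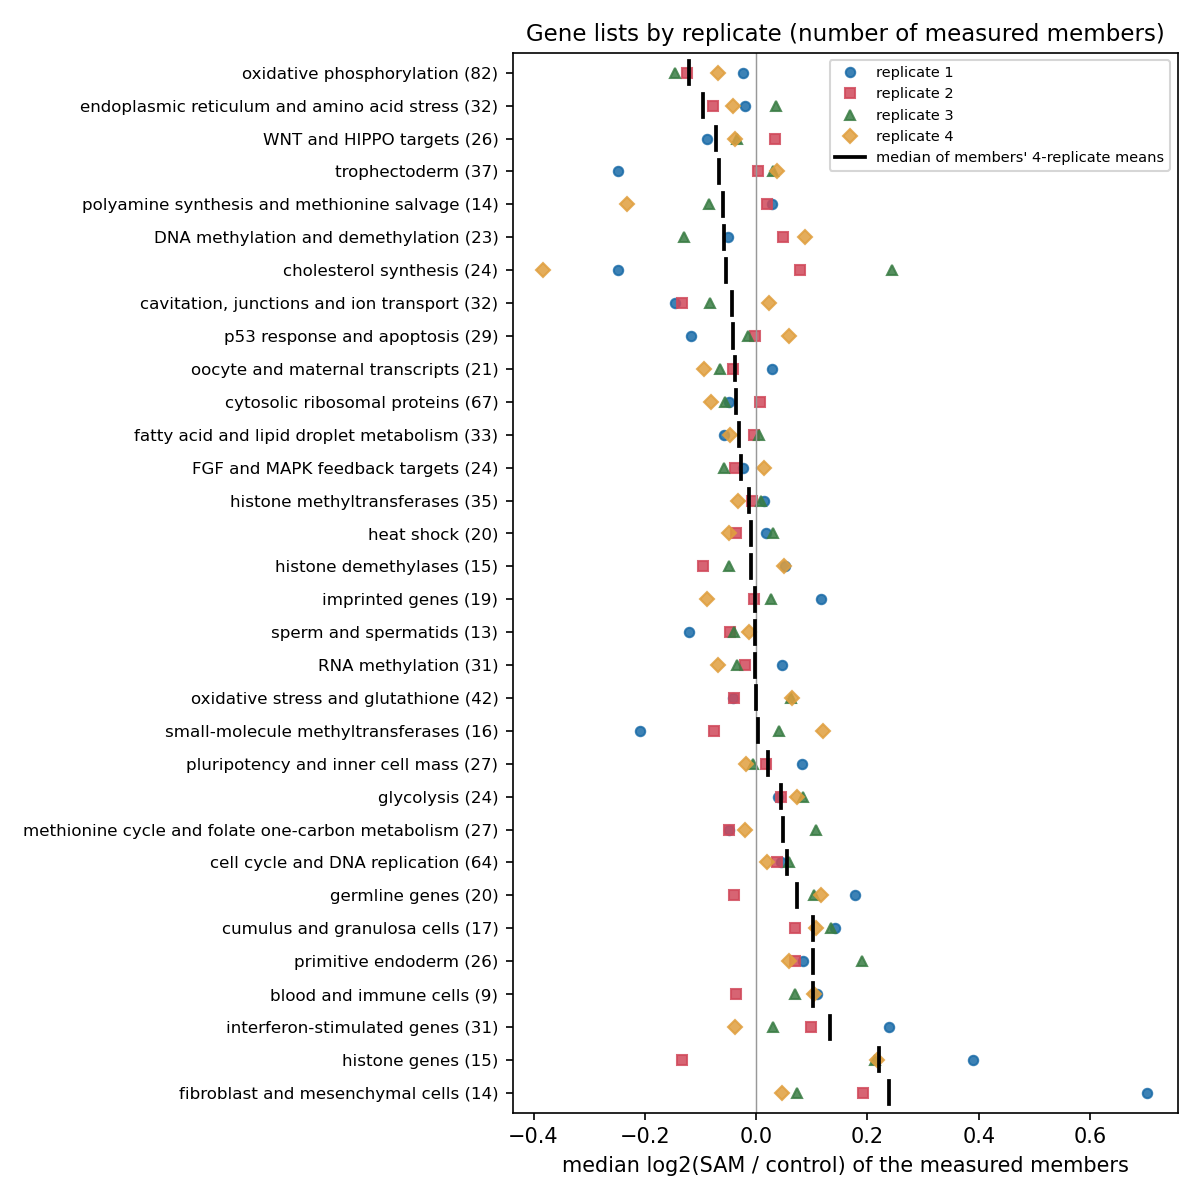
Median log2 ratio of SAM over control of each gene list's measured members, by replicate (symbols) and for the means over 4 replicates (vertical ticks), with the number of measured members in brackets. Oxidative phosphorylation lies lowest at -0.12 and the fibroblast and mesenchymal list highest at 0.24, where replicate 1 lies at 0.70.

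The fifth comparison set markers of other cells against the same ratios. Markers of fibroblast and mesenchymal cells had a median of 0.24 over 14 members (camera adjusted p = 0.150), with list medians of 0.70, 0.19, 0.07 and 0.05 in replicates 1 to 4. The cadherin *CDH2* was at 1.16 ± 0.47 (SE, n = 4), with 2.85 in replicate 1, 1.30 in replicate 2 and 0.23 in each of the others. *VIM* and *LUM*, the intermediate filament vimentin and the matrix proteoglycan lumican, were chosen after their values were seen. *VIM* was at 3.88, 2.31, -0.44 and 0.55 in replicates 1 to 4, and *LUM* at 3.46, 2.21, -0.46 and -0.07. *COL3A1*, a fibrillar collagen, was at 0.79 ± 0.22 and *COL1A1* at 0.24 ± 0.08, both dim. Over 8 arrays with a replicate block this list passed, at an adjusted p of 0.032, within a range of 0.030 to 0.800 over its alternatives.

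Markers of cumulus and granulosa cells, which surround the oocyte, had a median of 0.10 over 17 members (camera adjusted p = 0.074), with 4 higher and 0 lower at an unadjusted p under 0.05. The list's median lay between 0.07 and 0.14 in the 4 replicates, and fry called it at an adjusted p of 0.020, within a range of 0.019 to 0.800 over its alternatives. The highest of these came from camera with an estimated correlation, where the unadjusted p was 0.062. *SERPINE2*, a protease inhibitor, was at 0.66 ± 0.14 and *INHBA*, an inhibin subunit, at 0.41 ± 0.13 (SE, n = 4). Interferon-stimulated genes had a median of 0.13 over 31 members (adjusted p = 0.254), with medians of 0.24, 0.10, 0.03 and -0.04 in replicates 1 to 4, highest where *VIM* and *LUM* were highest. *TAP1*, a peptide transporter, was at -0.23 ± 0.07 and *PARP12* at 0.24 ± 0.08. Oocyte and maternal transcripts had a median of -0.04 over 21 members (adjusted p = 0.555), with *ZAR1L* at -0.42 ± 0.15. The next members by p went the other way, *TLE6* at 0.13 ± 0.06 and *WEE2* at 0.12 ± 0.06. *WEE2* was above background in 4 SAM and 1 control channels. Sperm and spermatid genes had a median of 0.00 over 13 members (adjusted p = 0.954), with *CRISP2* at 0.29 ± 0.07. Blood and immune genes had a median of 0.10 over 9 members (adjusted p = 0.626), with the haemoglobin chain *HBA* at 0.24 ± 0.07. With replicates 3 and 4 alone, chosen after seeing the data, limma called 0 probes, while 4567 had an unadjusted p under 0.05 and 403 of these were at least 1.5-fold, 266 higher and 137 lower.

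**Figure D3:**
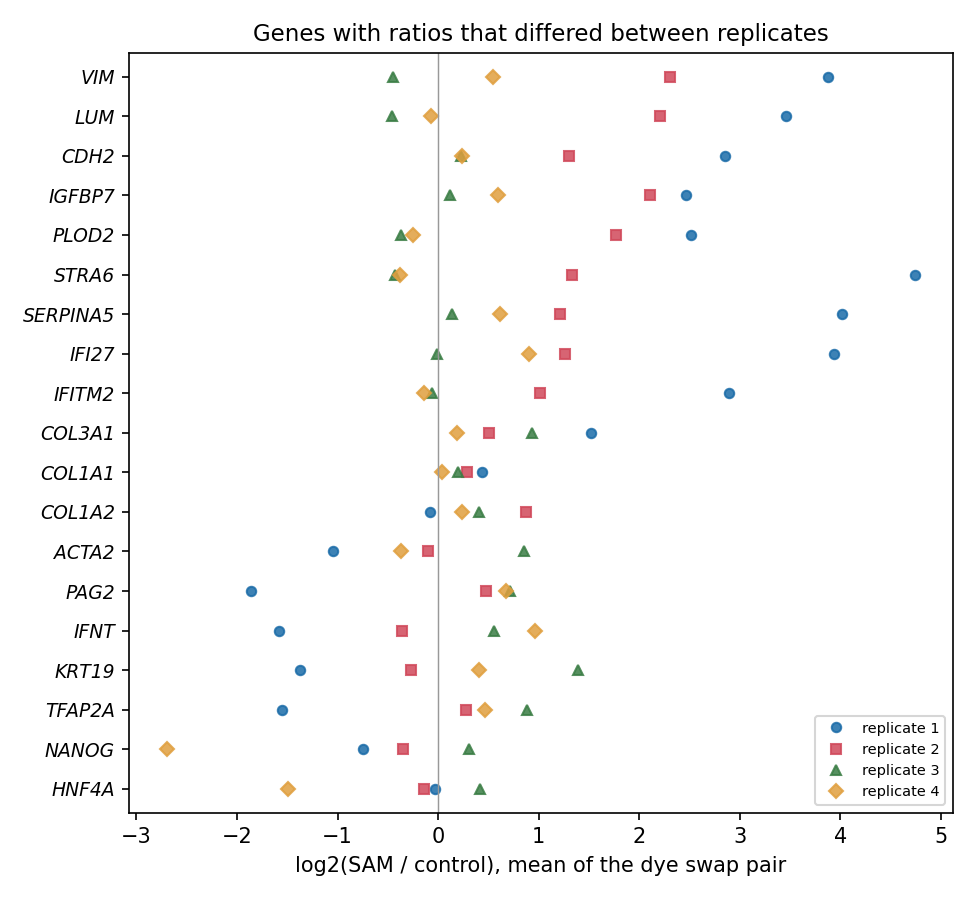
Log2 ratio of SAM over control by replicate (symbols, each the mean of a dye swap pair) for genes with ratios that differed between replicates, chosen after their values were seen apart from *COL3A1*, *COL1A1*, *CDH2* and *NANOG*. *VIM* reaches 3.88 in replicate 1 and 2.31 in replicate 2, and *NANOG* reaches -2.70 in replicate 4.

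The sixth comparison asked whether non-coding transcripts differed, as the series' title names long non-coding RNAs. By RefSeq class, 21 kept probes were for lncRNA genes and 224 for other non-coding genes or pseudogenes. Limma called 0 of these 245 probes, as it called 0 of 14444 protein coding ones, while 61 of the 245 had an unadjusted p under 0.05 (Fisher's exact test against protein coding probes, two-sided, p = 0.242). The 8-array fit with a block and a dye term called 8 of the 245, against 173 protein coding probes (Fisher's exact p = 0.011). All 8 were other non-coding genes or pseudogenes, and 0 of the 21 lncRNA probes were called. At an unadjusted p under 0.05 and at least 1.5-fold there were 4 (Fisher's exact p = 0.041), 1 of them an lncRNA probe. Fisher's test takes probes as independent, although all were read in the same pools, and its p-values were not adjusted over the thresholds. In simulation the 8-array fit also called unchanged genes above its nominal share. These p-values therefore do not establish that non-coding probes differed more often. Of the lncRNA probes, 1 was higher and 2 were lower at an unadjusted p under 0.05. These are named after their values were seen. LOC782977 was at 0.73 ± 0.25, LOC100337507 at -0.25 ± 0.07 and LOC100140121 at -0.17 ± 0.06 (SE, n = 4). The 189 pseudogene probes had a median of -0.06, with 6 higher and 50 lower at an unadjusted p under 0.05. The 12312 unnamed probes, 2246 of which had an unadjusted p under 0.05, were not classed here.

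The last comparison was technical and set the dyes against each other. Over the 8 arrays limma found a dye effect at 8294 probes, or 30.5% of those kept, with a median size of 0.20 on the log2 scale. The log2(SAM/control) means of the 4 arrays with SAM in Cy5 spread more widely over probes (SD 0.29) than those with SAM in Cy3 (SD 0.18). Fitted alone, the 4 arrays with SAM in Cy5 gave 2663 called probes and the 4 with SAM in Cy3 gave 0, with 10355 and 3780 at an unadjusted p under 0.05. Arrays of different replicates correlated across probes at a mean r of 0.454 when both had SAM in Cy5 and 0.205 when both had SAM in Cy3. Arrays of different replicates with opposite dyes correlated at a mean r of -0.02, from -0.14 to 0.16. Probes are not independent replicates. The mean SAM ratio and the dye effect correlated across probes at r = 0.483. Both come from the same 8 arrays. This value therefore follows from the unequal spreads of the 2 orientations and their correlation of r = 0.146, and adds nothing to them. Of the genes named above by the rule, *AHCY*, *MTR*, *DNMT3A*, *DNMT3B*, *KDM4B*, *KDM4C*, *SYCP3*, *H2AZ1*, *HSF2*, *TLE6*, *WEE2* and *HBA* had opposite signs in the 2 orientations. Others kept their sign but rested mostly on 1 orientation. Among them, *FAS*, *COX7A2L*, *HADHB*, *SETDB1*, *DDX4* and *DGAT2* lay between 0.02 and 0.09 with SAM in Cy3, against 0.52 to 0.82 with SAM in Cy5. Apart from the dyes, genes were read at their brightest probe, and at *LIN52*, *FMR1*, *MAT2A*, *AHCY*, *SAT1*, *DNMT3A*, *STAT3*, *LAMC1*, *MACROH2A1*, *ENO1*, *HK2*, *COX7A2L* and *MXRA7* at least 1 other kept probe pointed the other way.

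**Figure D4:**
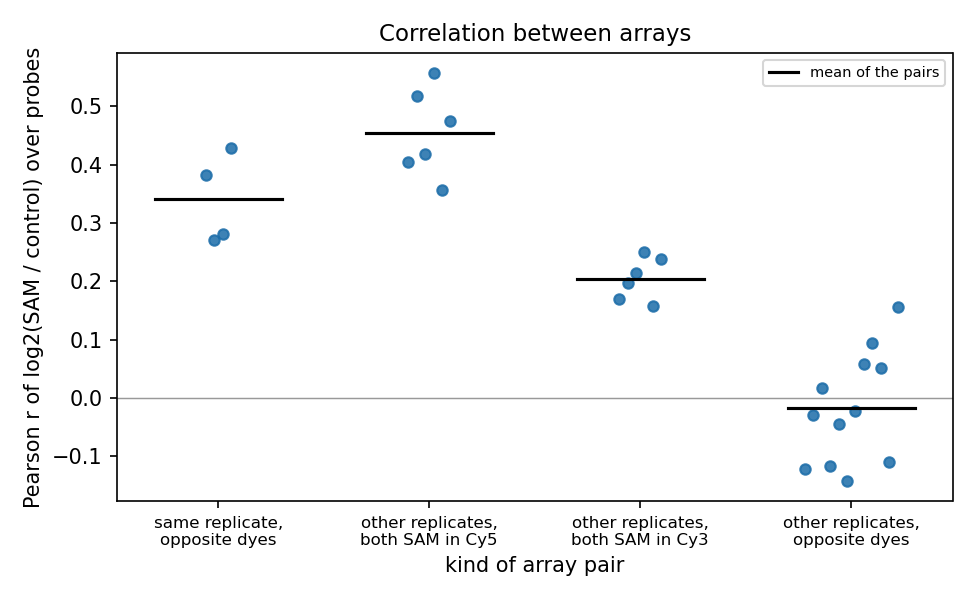
Pearson correlation over kept probes of log2(SAM/control) between pairs of arrays, by kind of pair, with points for pairs and lines for their mean. Pairs of other replicates with opposite dyes lie between -0.14 and 0.16, below the 4 swap pairs at 0.27 to 0.43.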

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

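The tests of dye effects and of oxidative phosphorylation in this part were chosen after the result was seen, as were the counts of sign arrangements for all probes and genes past a threshold and for probes at an unadjusted p under 0.05.

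In 7 of the 158 sets of 4 values tested, 1 replicate stood far from the other 3, close to the 5% that chance gives. Among 116 named genes there were 6. The log2 ratio of *CARS1* was -0.41 in replicate 2, against -0.66 to -0.62 in the others. *MAT2A* was at -0.83 in replicate 4, against -0.40 to -0.35. *COQ5* was at -0.63 in replicate 2, against -0.19 to -0.12. *GADD45B*, a stress gene linked to DNA demethylation, was at 0.11 in replicate 4, against -0.44 to -0.36. *MBD1*, a methyl-CpG binding protein, was at 0.75 in replicate 4, against 0.13 to 0.20. *WTAP* was at 0.093 in replicate 3, against 0.38 to 0.41. Among 32 gene lists there was 1, the trophectoderm list, whose median was -0.25 in replicate 1, against 0.00 to 0.04 in the others. None of 10 measures of array brightness and spread was set apart. The detection limits, highest at 323.3 in Cy3 and 542.3 in Cy5 on the array with SAM in Cy5 of replicate 2, were not among these measures.

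The 4 replicates allow 8 arrangements of their signs, too few for a share under 0.05. At an unadjusted p under 0.05 the real arrangement gave 5478 probes and the highest other 2472, so 1 of 8 gave as many. With the added limit of 1.5-fold the counts were 160 and 70, again 1 of 8. For genes called over 8 arrays with a dye term they were 101 and 1, again 1 of 8. Adjusted calls of probes and of genes were 0 in all 8 arrangements. Of the gene lists, 2 passed in the real arrangement and up to 5 in another, and 7 of 8 arrangements gave at least as many.

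The excess of probes at an unadjusted p under 0.05 could come in part from dye effects that do not cancel within a swap pair. The SAM estimate from some replicates correlated across probes with the dye estimate from the others at a mean r of 0.346, from 0.330 to 0.362 over the ways of choosing them. Such an effect, where the replicates share it, turns with a replicate's sign as an effect of SAM would, so the counts above do not decide between them. An effect of SAM shared by the pools also remains open.

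For the lower oxidative phosphorylation genes, a bias that follows probe brightness was argued against, since the list's median lay at percentile 0.00 of the matched random lists. Genes of the list moving together between pools stay open as an account. The call was lost with an estimated correlation of 0.07 (camera unadjusted p = 0.164, adjusted p = 0.800), but this loss does not decide it. For cumulus and granulosa markers the estimated correlation was -0.03, below the preset one. Their unadjusted camera p nevertheless rose, from 0.0070 to 0.062. No list passed in that setting, where 0.800 was the lowest adjusted p. Dye effects as the whole account cannot be told apart from SAM here. They turn sign with the dyes, and against them the list passed as lower in the 4 arrays with SAM in Cy3 alone (camera adjusted p = 0.0071). It passed there only at the preset correlation, with a camera unadjusted p of 0.163 at an estimated one. With SAM in Cy5 alone the list did not pass, although its median was -0.17. On the 4 arrays with SAM in Cy3 its medians averaged -0.068 with an SE of 0.034, not more than 2 SE below 0. Of these 4 medians, 1 was above 0. Of the list's 82 genes 47, or 57.3%, had the same sign in both orientations, against 54.0% of all genes. A part from the dyes stays open too. So does chance, since 7 of 8 sign arrangements gave at least as many passing lists as the real one. An effect of SAM on these genes remains open as a hypothesis.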

How the results depend on the processing

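Of the alternatives, the detection limit from median and MAD and replicates 3 and 4 alone were chosen after seeing the data. The cause of the changes below was not tested, except that fitting the 8 arrays separately counts technical swaps as added observations. List calls in the fits tested with cameraPR also come with that change of list test. Limma called 0 probes and genes except in the following fits. Probes past the threshold numbered 556 over 8 arrays with a replicate block, 468 with no replicate block, 303 with a block and a dye term, 2663 with SAM in Cy5 alone and 802 with array weights. Genes numbered 217, 177, 101, 927 and 168 in the same order, and named genes 23, 20, 18, 47 and 25. Probes at an unadjusted p under 0.05 and at least 1.5-fold numbered 160 in the main setting, 139 with trend and robust options as the lowest count, and 183 without replicate 3 to 296 without replicate 2 with a replicate left out. They numbered 1341 with SAM in Cy5 alone, 304 with array weights and 403 with replicates 3 and 4 alone. At that threshold 4 non-coding probes were counted, against 0 adjusted. The dye effect kept within 1.5 times its count under median centring, with 6107 probes.

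Gene lists passing, 2 in the main setting, numbered 1 to 4 with a replicate left out, 4 with the replicate block and with no replicate block, 1 with array weights, with trend and robust options and with fry, and 0 with SAM in Cy5 alone, with the deposited values and with an estimated correlation. Oxidative phosphorylation did not pass with SAM in Cy5 alone (adjusted p = 0.278), the deposited values (0.051), fry (0.363) or an estimated correlation (0.800), and passed with SAM in Cy3 alone (0.0071) and with each replicate left out. Ribosomal proteins ranged from 0.0017 without replicate 2 to 0.137 without replicate 1, and were at 0.322 with SAM in Cy5 alone, 0.106 with the deposited values, 0.071 with array weights, 0.064 with trend and robust options, 0.419 with fry and 0.800 with an estimated correlation. Cumulus and granulosa markers passed without background correction (0.032), with median centring (0.039), no filter (0.019), the MAD limit (0.023), the mean over probes (0.023), the replicate block (0.032), no replicate block (0.030) and fry (0.020). Fibroblast and mesenchymal markers passed with the replicate block (0.032) and no replicate block (0.030), and ranged from 0.044 without replicate 3 to 0.520 without replicate 1. Histone genes ranged from 0.021 without replicate 2 to 0.562 without replicate 1, and cholesterol synthesis from 0.0099 without replicate 3 to 0.873 without replicate 4. Other settings left each list on its side of the threshold. Of 764 list settings 739 kept their side, 12 lost and 13 gained a call, and 76 turned the direction of an uncalled list. Of 2506 settings of named genes 133 gained a call and 25 turned direction, among them *AHCY* in 3 and *DNMT3B* in 2. The replicate block changed no other list's call. Signal over background limits the dim genes: 8393 of the 27175 kept probes were above background in all 16 channels.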

Other observations

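The tests of *VIM*, *LUM* and *CDH2* in this part were chosen after the result was seen, as were the genes named here, apart from *CDH2*, *NANOG*, *TKDP1*, *MSX2*, *TEAD3*, *ACAT2*, *COL1A1* and *COL3A1*, which the rule named.

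Single replicates held larger differences than the mean of 4. The number of genes at least 2-fold higher in the SAM pool was 122, 45, 27 and 31 in replicates 1 to 4, and at least 2-fold lower 67, 11, 7 and 15. In both replicates 1 and 2, 17 genes were at least 2-fold higher, and all 17 were under 2-fold in replicates 3 and 4. Besides *VIM*, *LUM* and *CDH2*, these included *IGFBP7*, a secreted growth factor binding protein, at 2.47 and 2.11, *PLOD2*, a collagen lysyl hydroxylase, at 2.51 and 1.77, *STRA6*, a retinol transporter, at 4.74 and 1.33, and *SERPINA5*, a protease inhibitor, at 4.01 and 1.21. The interferon-induced *IFI27* was at 3.94 and 1.26 and *IFITM2* at 2.90 and 1.01. In replicate 1 some trophoblast genes were lower in the SAM pool, among them the trophoblast interferon *IFNT* at -1.59, the pregnancy-associated glycoprotein *PAG2* at -1.86, *KRT19* at -1.38 and *TFAP2A* at -1.56, while in replicates 3 and 4 these 4 were above 0. Others were not lower in replicate 1, with *TKDP1* at 1.08, *MSX2* at 0.15 and *TEAD3* at 0.13, and the median of the fixed trophectoderm list there was -0.25. In replicate 4 *NANOG* was at -2.70 and *HNF4A*, an endoderm factor, at -1.49. In replicates 1 and 4 the sterol genes *HMGCS1*, at -0.91 and -1.19, and *ACAT2*, at -1.16 and -1.10, were lower.

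The high *VIM*, *LUM* and *CDH2* ratios of replicates 1 and 2 were unlikely to be the fault of 1 array or dye, since the lowest of the 6 values over both arrays of replicate 1 was 2.33. An effect of SAM of like size in all pools was set against the 17 genes at least 2-fold higher in replicates 1 and 2, taken without regard to replicates 3 and 4. They averaged 2.29 in replicates 1 and 2 and -0.015 in replicates 3 and 4, with an SE of 0.08 over genes. That SE takes genes read in the same pools as independent, so it does not measure the spread between pools. Choosing genes as high in replicates 1 and 2 also favours lower values in the others. The ratios of these genes thus differed between the pools, but the test does not exclude such an effect. An effect of SAM that differed between pools was not tested and stays open. RNA from fibroblast or mesenchymal cells, or embryos with more such cells, may have been present in those SAM pools, but the other 11 members of the fixed list had a median of 0.18 in replicate 1. In replicate 1 *COL1A2*, at -0.08 with a control level of 10.96, and *ACTA2*, at -1.04, were not higher. *COL3A1*, at 1.52, was higher there, and *COL1A1* was at 0.43, both dim in controls at a mean log2 brightness of 7.92 and 7.93. In replicate 2 *COL1A2* was at 0.87, *COL3A1* at 0.50, *COL1A1* at 0.29 and *ACTA2* at -0.10. The members thus went both ways, and the source stays open. RNA from cumulus or granulosa cells stays open too, with a median of 0.14 for that list in replicate 1 but only 4 of its 17 members above background in all channels.

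Pseudogene probes leaned lower in the SAM pools in the mean over replicates. Their median of -0.06 lay at percentile 0.00 of 10000 sets of probes matched on brightness, whose median was -0.01. Random sets take probes as independent, so the percentile makes no allowance for pseudogene probes that move together between pools. No explanation was tested.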
